A study of Caenorhabditis elegans with 4 samples.

How the data were processed

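Whole worms of 2 groups, on OP50 and on *M. furfur* for 6 h, were compared, with 2 libraries per group, and the groups and replicate numbers were taken from the sample titles. The column headings of the deposited tables number the libraries of each group 1 and 3, where the titles number them 1 and 2; why they differ is not given in the sources used here. Per the labels' protocols, total RNA was extracted from about 200 worms per sample, messenger RNA was selected on poly(A) beads, and libraries were made with a SMARTer stranded kit. The deposited values are raw read counts per gene, 1 table per library, with no normalization by the authors. Per the submitters' processing notes, Trim Galore 0.6.6, Trimmomatic 0.39, cutadapt 3.1, STAR 2.7.9b and featureCounts 2.0.1 were used, with the builds ce11 and WBcel235. The strand setting, the treatment of reads that map to several places, and the read layout are not given in the sources used here. Values of overlapping genes, of antisense pairs and of near-identical copies (vitellogenins, major sperm proteins, and some collagen, F-box and histone genes) are therefore uncertain as to which gene the reads came from.

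The tables list 46904 genes with symbols, identifiers and coordinates, and 0 entries without a gene. Coordinates are those of the deposited tables. Of the identifiers, 46817 were found in the Ensembl annotation of the same build, all on the same chromosome and 32349 with the same start and end. Totals ran from 35284856 to 43258400 counts per library, so that 3 reads, the floor used for genes without a read, correspond to 0.0694 to 0.0850 CPM per library. This floor covers counting error only. A gene without a read in one group is given as a bound against 3 reads over both libraries of that group. Of the called genes, 21 were of this kind.

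Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with default settings by group, which left 15956. TMM factors were 0.923 and 0.946 for OP50 replicates 1 and 2, and 1.09 and 1.05 for *M. furfur* replicates 1 and 2. A quasi-likelihood model with the group as its only term was fitted, log2 fold changes (*M. furfur* minus OP50) were tested with the quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The common biological coefficient of variation was 0.101 and the prior degrees of freedom 6.37. CPM values are scaled with the TMM factors, means are given with the SD over 2 libraries, and log2 fold changes with the SE of the model. Adjusted p-values of single genes come from this test, those of lists from camera.

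The gene lists, the rule for the genes named and the alternatives were fixed before the data were examined. The 49 lists cover immune effectors, stress and detoxification, metabolism, reproduction, cuticle and tissue markers, and were matched to symbols exactly; 4 listed names were not matched. Lists with at least 5 tested members (48 lists) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and the preset correlation of 0.01, and p-values were adjusted over the lists. At this setting 24 lists were called, 8 up and 16 down. Camera compares the members of a list with the other tested genes, so its directions are relative to those genes. With the correlation estimated from the residuals, which rest on 2 libraries per group, 0 lists were called, and the smallest adjusted p was 0.612. With an estimated correlation camera also tests each list on the 2 residual degrees of freedom, and at the preset correlation on far more. It could therefore hardly call any list, and a call lost at that setting says little about the list. Such a loss cannot be put down to correlation between genes rather than to the few libraries. The glycolysis list had an estimated correlation of -0.022, below the preset 0.01, yet its camera p before adjustment went from 4.75e-06 to 0.0348. At the preset correlation camera on ranks called 24 lists. The fry test, which asks whether the members of a list move one way on balance without comparing them with other genes, called 28. It added lysozymes, the intracellular pathogen response, chitinase-like proteins, cytochromes P450, antioxidant enzymes, the mitochondrial unfolded protein response, DAF-16-activated genes, proteases, insulin-like peptides and collagens, and did not call the hypoxia, ribosomal protein, FMRFamide-like, germ cell, neuronal and mitochondrially encoded lists. Named genes are the 10 largest rises and the 10 largest falls among called genes with both *M. furfur* libraries on one side of both OP50 libraries and a mean of at least 5 CPM, up to 4 members with the smallest p of each list, and a fixed set of reporter and pathway genes. The remaining tested members are summarised as counts.

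Counts were simulated with each gene's mean over the 2 OP50 libraries and the real library sizes. Dispersions were those of the comparison of *M. furfur* with OP50. Of 15956 genes 200 were changed, all drawn from genes with a mean of at least 1 CPM on OP50. The test recovered 48% of genes changed 1.5-fold, 66% of those changed 2-fold, 98% of those changed 4-fold and 100% of those changed 8-fold. There were 9 false calls. These shares do not cover genes below that mean. Of 20 simulated lists without a change 0 were called, and both changed lists were called. Genes were simulated independently, so these lists do not test camera on correlated genes.

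The alternatives were size factors of the DESeq2 type (RLE), upper quartile factors, library size alone, no filter on low counts, at least 10 CPM in 2 libraries, DESeq2 1.42.0, limma voom, a robust fit, an adjusted p threshold of 0.01, a minimum change of 1.5-fold, leaving out each library, the replicate number as a block, removal of a loess trend of each library on gene length, both of these together, and leaving out mitochondrial, ribosomal RNA and histone genes. Summing near-identical vitellogenin copies was added after seeing the data. Enrichment of Gene Ontology terms from the deposited tables, used in the closing section only, was chosen after seeing the data.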

Results

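RNA was measured by sequencing in whole wild-type *Caenorhabditis elegans* (strain N2 Bristol) that were 3 days old and had spent 6 h on plates covered either with *Malassezia furfur*, a lipid-dependent yeast of mammalian skin, or with *Escherichia coli* OP50, the standard laboratory food. Each group held 2 libraries made from about 200 worms each. The OP50 libraries held 43258400 and 41031746 counts in replicates 1 and 2, and the *M. furfur* libraries held 35284856 and 37809782. Replicates of a group correlated at 0.991 (OP50) and 0.990 (*M. furfur*) over log2 CPM (counts scaled to library size) of the tested genes, and libraries of different groups at 0.941 to 0.947. These correlations are across genes, which are not independent replicates. No pair of libraries agreed within sampling noise, so all 4 were kept as separate samples. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

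The comparison asked which transcripts are regulated when worms meet the yeast. On *M. furfur*, gene lists of p38 MAP kinase-dependent immunity, glutathione and glucuronic acid conjugation, yolk, body wall muscle, proteasome and propionate breakdown were called as lower at camera's preset correlation, and those of the endoplasmic reticulum unfolded protein response, autophagy, lipases and moulting as higher. So were those of nuclear hormone receptors (69 of 201 genes higher) and FMRFamide-like neuropeptides (10 of 30); with library size alone 86 and 17 of these genes were higher. With an estimated correlation none of these lists was called (adjusted p = 0.612 to 0.672). The test at that setting rests on 2 residual degrees of freedom and could hardly have called any list, so it decides little here. Of 15956 genes tested, 3646 were higher and 3605 lower on *M. furfur* (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 2 per group), which is 45.4% of those tested. A change of 2-fold or more was found for 1609 of the higher and 1379 of the lower genes. The split between directions depended on scaling: with library size alone in place of TMM factors, 5414 genes were higher and 2333 lower, because log2 fold changes moved up by a median of 0.19. Changes below are given with TMM factors, relative to that shift. Against a 1.5-fold minimum change (glmTreat), 1497 genes were higher and 1331 lower.

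**Figure D1:**
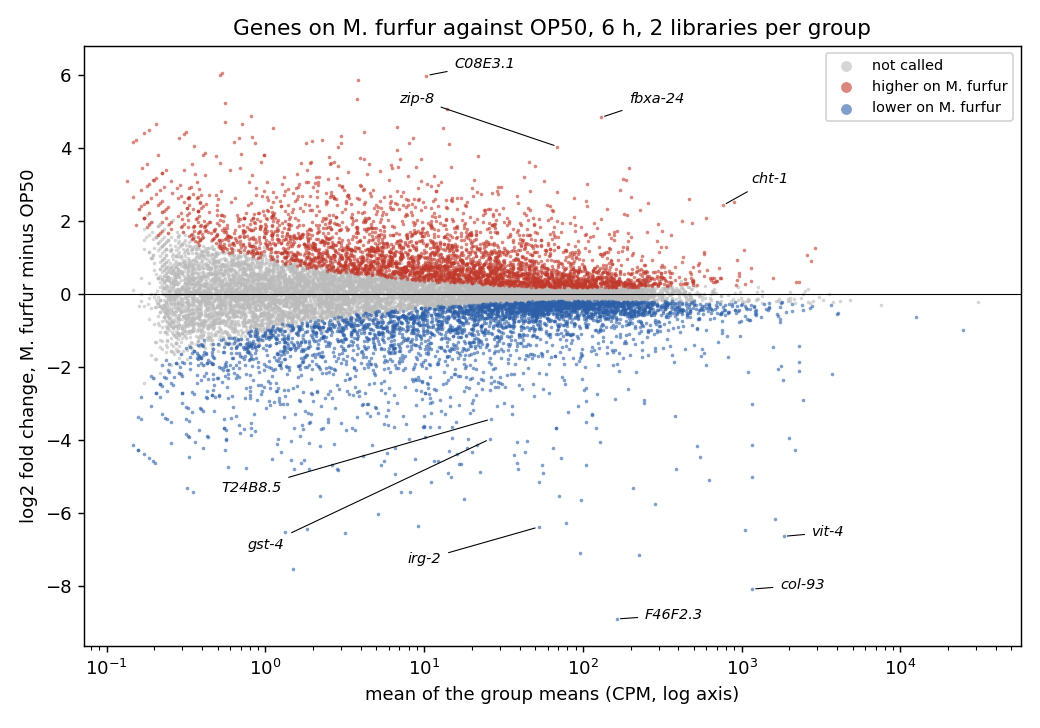
Log2 fold change (*M. furfur* minus OP50) of each tested gene against the mean of both group means in CPM on a log axis, with called genes coloured by direction and genes without a read in one group left out. The called genes were 3646 higher and 3605 lower, with F46F2.3 and col-93 at the bottom and C08E3.1 near the top.

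Among genes with at least 5 CPM on average, C08E3.1 (chromosome II, 1633806 to 1634089, ce11/WBcel235) rose most, from 0.318 ± 0.060 to 20.3 ± 4.6 CPM (SD, n = 2 per group), a log2 fold change of 5.99 ± 0.26 (SE; adjusted p = 8.97e-07). Its neighbour C08E3.13 (chromosome II, 1631995 to 1633850), on the opposite strand and with an annotated end that overlaps it, rose by 4.28. How reads over the overlap were counted depends on settings that are not given in the sources used here. T23E7.6 rose by 5.08 and C18H7.1 by 4.59 on the log2 scale. The F-box gene fbxa-24 (chromosome II, 3816686 to 3818238) rose from 8.80 ± 0.34 to 252.0 ± 12.4 CPM, and zip-8 (chromosome III, 6478961 to 6481226), which encodes a bZIP transcription factor, from 7.92 ± 1.37 to 130.5 ± 4.0 CPM. The others of the 10 were Y62F5A.10, the invertebrate-type lysozyme gene ilys-2, the trehalase gene tre-5, and the thioredoxin gene trx-3, with log2 fold changes between 3.94 and 4.54. The largest fall was that of F46F2.3 (chromosome X, 15259579 to 15260290), from 327.1 ± 5.2 to 0.680 ± 0.146 CPM, a log2 fold change of -8.91 ± 0.12 (SE; adjusted p = 7.65e-09). The cuticle collagen genes col-93, col-98, col-80, col-94 and col-101 made up 5 of the 10 largest falls: col-93 fell from 2322 ± 166 to 8.53 ± 1.6 CPM and col-101 from 3214 ± 74 to 44.4 ± 19.8 CPM. The yolk gene vit-4, the infection response gene irg-2, C06B3.7 and the acyltransferase gene oac-32 completed that group, with log2 fold changes between -7.09 and -6.35.

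All tested immune genes of the PMK-1-dependent list fell. PMK-1 is the p38 MAP kinase that keeps many intestinal defence genes active, and all 9 tested members were lower (9 also when adjusted over the list alone), with a median log2 fold change of -3.43 (camera adjusted p = 4.88e-06 at the preset correlation). The lysozyme gene lys-2 fell from 106.0 ± 13.9 to 4.11 ± 0.17 CPM, T24B8.5 from 48.2 ± 0.9 to 4.49 ± 1.63 CPM, and the lectin gene clec-85 fell by 2.27 on the log2 scale, while K08D8.5 had a log2 fold change of -3.95; catp-3, listed under its sequence name, fell by 4.42. All 6 tested infection response genes (irg) also fell (6 adjusted over the list alone; camera adjusted p = 0.000443), among them irg-1, from 28.8 ± 13.2 to 0.885 ± 0.116 CPM, irg-7 by 1.68, irg-4 by 4.02 and irg-5 by 1.47. The genes irg-4 and irg-5 belong to both lists. With an estimated correlation neither list was called (adjusted p = 0.612 with an estimated correlation for both). The transcript of pmk-1 itself rose, from 17.5 ± 0.6 to 34.7 ± 0.5 CPM (log2 fold change 0.99 ± 0.09 SE, adjusted p = 4.89e-05). The transcript of zip-2, a bZIP factor upstream of irg-1, stood at 230.1 ± 12.1 CPM on OP50 and 214.3 ± 7.7 CPM on *M. furfur* (adjusted p = 0.284).

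The other families of immune effectors moved in both directions, and camera called none of them. Their lists share members with the PMK-1-dependent list, namely the lysozyme gene lys-2 and the lectin genes clec-67 and clec-85. The fry test called the lysozymes as lower (adjusted p = 0.0297). It called the chitinase-like and intracellular pathogen response lists, described below, as higher (0.0226 and 0.0385). Of the caenacins and nlp-29-type antimicrobial peptides, which epidermal fungal infection is known to induce, 10 of 20 rose and 5 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.285). Within it nlp-31 rose by 1.61, nlp-34 by 2.98 and nlp-29 by 1.0 on the log2 scale, nlp-24 fell by 2.72 and nlp-33 by 1.98, cnc-2 had a log2 fold change of 0.51 ± 0.36 (SE) and cnc-4 one of -0.36 ± 0.26, neither called; cnc-4 passed as lower without *M. furfur* replicate 1 (adjusted p = 0.0476). Of the fungus-induced fip and fipr genes 4 of 19 rose and 5 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.515), and 5 and 4 with library size alone, with fip-5 higher by 1.81 and fipr-22 lower by 1.53 on the log2 scale. Defensin-like, saposin-like and thaumatin-like genes had 7 of 24 higher and 6 lower (7 and 6 adjusted over the list alone, camera adjusted p = 0.66), with a median of 0.12 and a mean of -0.08. With library size alone 9 were higher and 4 lower, and the median was 0.31. Within this list spp-8 rose by 2.1, abf-2 by 1.6, and spp-17 fell by 1.51. Among C-type lectins 31 of 143 rose and 43 fell (33 and 45 adjusted over the list alone; camera adjusted p = 0.553), with a median of -0.09 and a mean of 0.07. Scaled by library size alone, 41 lectin genes were higher and 36 lower, and the median was 0.09. There clec-266 rose by 2.41 and clec-48 fell by 1.99, and clec-60 stood at 0.546 and 0.655 CPM (adjusted p = 0.636). Of the lysozymes 3 of 13 rose and 6 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.302), including lys-1, lower by 1.91, lys-7, lower by 1.66, and ilys-5, lower by 2.99.

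Chitin is a component of fungal cell walls, and the chitinase gene cht-1 rose from 238.8 ± 7.6 to 1288 ± 27 CPM (log2 fold change 2.43 ± 0.08 SE, adjusted p = 2.69e-07), while cht-3 stood at 313.5 ± 23.6 and 313.8 ± 17.2 CPM. With 4 tested members, of which 3 rose and 0 fell (3 and 0 adjusted over the list alone), chitinases were too few for a list test. Of the chitinase-like chil genes, some of which oomycete infection is known to induce, 6 of 12 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.217); chil-23 rose by 3.36 and chil-22 by 2.1, and chil-7 fell by 3.21 on the log2 scale. The marker chil-27 had between 1 and 8 counts per library and was not tested. Of the genes of the intracellular pathogen response, known from microsporidia and virus infection, 14 of 33 rose and 5 fell (15 and 5 adjusted over the list alone; camera adjusted p = 0.153), with pals-32 higher by 4.43, pals-24 lower by 2.46 and pals-23 lower by 2.23. The reporter gene pals-5 was low in both groups, at 0.393 CPM on OP50 and 0.255 CPM on *M. furfur* (adjusted p = 0.345).

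Of the glutathione S-transferases, 22 of 44 fell and 5 rose (22 and 5 adjusted over the list alone), with a median log2 fold change of -0.63 (camera adjusted p = 0.000457). The SKN-1 reporter gene gst-4 fell from 48.7 ± 8.6 to 3.09 ± 0.69 CPM, gst-24 from 82.3 ± 13.8 to 4.09 ± 0.25 CPM and gst-27 by 2.27 on the log2 scale. Of the UDP-glucuronosyltransferases, 29 of 62 fell and 11 rose (32 and 13 adjusted over the list alone), with a median of -0.71 that did not move when the member without a read on OP50 was set to its bound (camera adjusted p = 0.00196); ugt-26 fell from 138.6 ± 49.9 to 2.97 ± 0.01 CPM and ugt-28 by 2.55. Both calls were lost with an estimated correlation (adjusted p = 0.612 with an estimated correlation). Of the cytochromes P450, 24 of 64 fell and 10 rose (24 and 10 adjusted over the list alone; camera adjusted p = 0.091, 0.0114 with library size alone, and 0.612 with an estimated correlation); cyp-33C8 fell by 2.90, cyp-35A2 by 1.07, and cyp-37B1 rose by 3.49. The transcript of skn-1 stood at 192.8 ± 9.1 CPM on OP50 and 165.8 ± 22.8 CPM on *M. furfur* (adjusted p = 0.0992); without *M. furfur* replicate 2 it passed as lower (adjusted p = 0.0229), as it did with the gene length trend removed (0.0226). Of the antioxidant enzymes 13 of 27 fell and 4 rose (13 and 8 adjusted over the list alone; camera adjusted p = 0.255; median -0.12; 11 lower, 8 higher and a median of 0.08 with library size alone). Within them the methionine sulfoxide reductase gene msra-1 fell by 3.52, sod-3 by 1.5, sod-1 by 0.75 and prdx-2 by 0.69. Metal handling genes had 6 of 20 higher and 7 lower (6 and 7 adjusted over the list alone; camera adjusted p = 0.403; median -0.18, and 0.01 with library size alone), with the metallothionein gene mtl-1 higher by 1.37 and cdr-2 lower by 3.17. Hypoxia and hydrogen sulfide genes were lower for 4 of 11 and higher for 0 (4 and 0 adjusted over the list alone; camera adjusted p = 0.0485), with rhy-1 lower by 2.0 and cysl-2 by 0.80. That call was lost with an estimated correlation (adjusted p = 0.672 with an estimated correlation), with library size alone (0.0829), and without OP50 replicate 2 (0.138) or *M. furfur* replicate 1 (0.0511) or 2 (0.124).

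In the list of the unfolded protein response of the endoplasmic reticulum 11 of 18 rose and 4 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.0395), and 12 rose and 1 fell with library size alone. The chaperone gene hsp-3 rose from 621.6 ± 15.9 to 1446 ± 10 CPM, and the folding genes pdi-2 by 1.14, pdi-6 by 1.03 and dnj-27 by 1.22 on the log2 scale. In contrast the other BiP gene, hsp-4, the usual reporter of this response, had a log2 fold change of -0.19 ± 0.07 (SE; adjusted p = 0.0473), which turned to 0.00 with library size alone and was not called when any one of the 4 libraries was left out (adjusted p = 0.102 to 0.209), with upper quartile factors (0.081) or with no filter on low counts (0.0659). The list was not called without OP50 replicate 2 (0.094) or *M. furfur* replicate 2 (0.0785), nor with an estimated correlation (adjusted p = 0.612 with an estimated correlation). Of the proteasome subunits 26 of 33 fell and 0 rose (28 and 0 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 4.6e-06). With library size alone 20 were lower and 1 higher, and the median was -0.23. Among them pas-4 fell from 137.1 ± 2.5 to 77.2 ± 0.2 CPM and pas-2 by 0.81. Of the autophagy and lysosome genes 19 of 29 rose and 1 fell (19 and 2 adjusted over the list alone; camera adjusted p = 0.00284), led by epg-2, from 193.4 ± 4.1 to 471.9 ± 1.7 CPM, and atg-16.2, higher by 1.26. Of the ribosomal proteins 40 of 80 fell and 5 rose (46 and 6 adjusted over the list alone; camera adjusted p = 0.000165), by small amounts, with a median of -0.23. With library size alone 12 ribosomal protein genes were higher and 9 lower, and the median was -0.04. There rps-27 fell by 0.61 and rpl-11.1 by 0.60. All 3 of these calls were lost with an estimated correlation (adjusted p = 0.612 with an estimated correlation for the proteasome and autophagy, 0.689 for ribosomal proteins).

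Heat shock proteins had 3 of 16 genes higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.918; median -0.07, 0.12 with library size alone, and mean 0.15). Among them hsp-12.6 rose by 2.98, hsp-110 fell by 0.57 and hsp-70 fell by 1.48, and hsp-16.2 stood at 9.83 ± 2.46 and 9.70 ± 1.01 CPM. Of the genes of the mitochondrial unfolded protein response 4 of 11 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.255; median -0.12; 2 lower, 2 higher and a median of 0.07 with library size alone); atfs-1 fell by 0.74 and hsp-60 by 0.47, and the reporter hsp-6 stood at 463.8 ± 1.5 and 426.9 ± 43.3 CPM (adjusted p = 0.289). Genes activated by DAF-16, the FOXO factor of insulin signalling, had 6 of 12 higher and 4 lower (6 and 4 adjusted over the list alone). The camera adjusted p was 0.422, with lea-1 higher by 0.93 and fat-5 lower by 2.59. The list holds daf-16 itself, counted among the 6 higher. The transcript of daf-16 rose by 0.27, a call lost without OP50 replicate 1 (adjusted p = 0.0997) or *M. furfur* replicate 2 (0.16), and with the gene length trend removed (log2 fold change 0.14, adjusted p = 0.218). Of the DAF-16-repressed dod genes 5 of 7 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.0176, and adjusted p = 0.612 with an estimated correlation); dod-24 fell by 2.98 and dod-17 by 3.1, and dod-22 rose by 1.94.

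**Figure D2:**
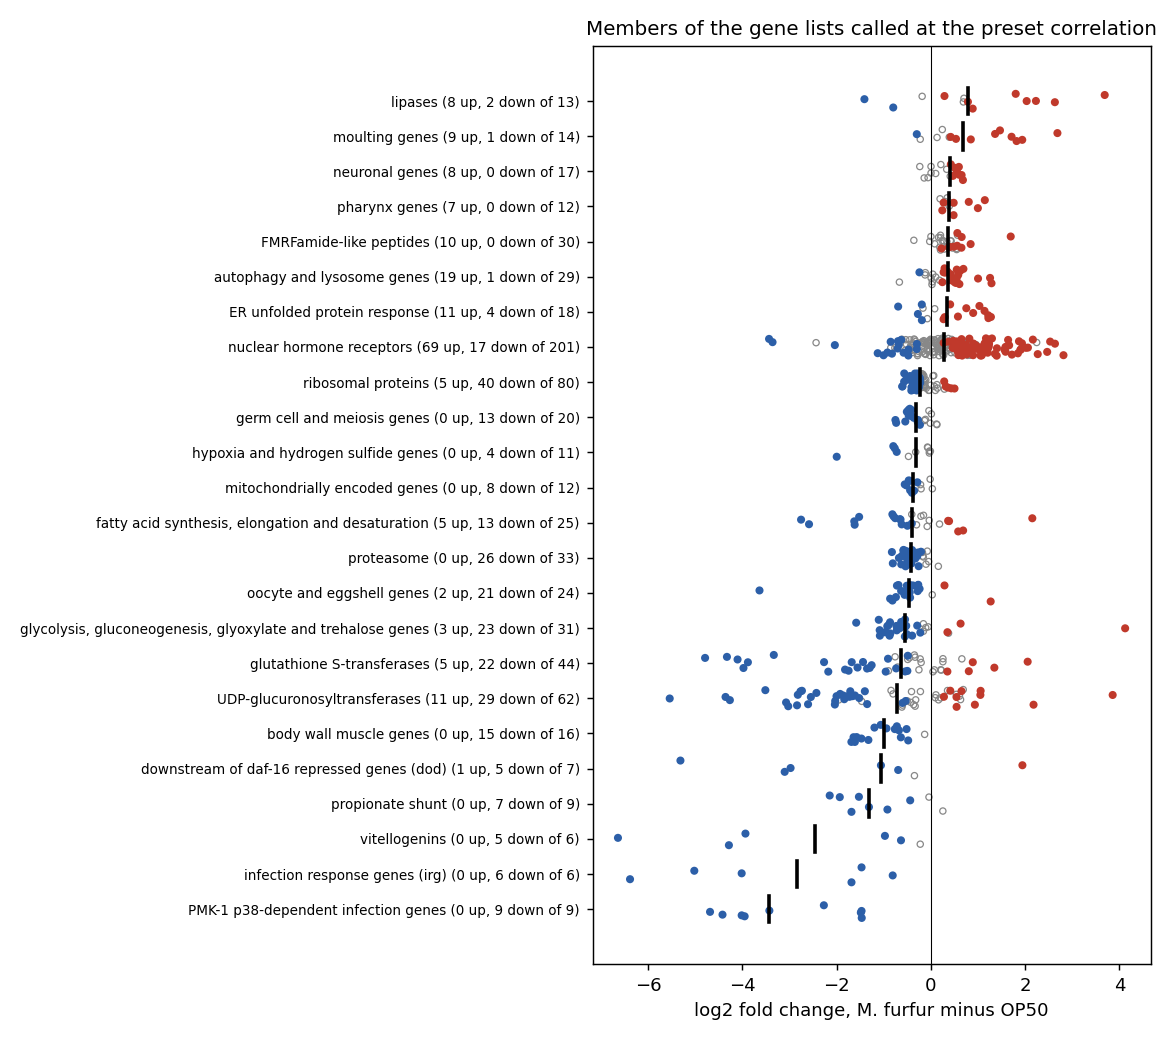
Log2 fold change (*M. furfur* minus OP50) of each tested member of the 24 lists called at the preset correlation, with filled points for called genes, open points for the rest, black bars for medians, and members without a read in one group left out of the points. The medians run from -3.43 for the PMK-1-dependent genes to 0.79 for the lipases, and no list was called with an estimated correlation.

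Of the genes of the propionate shunt, which worms use when vitamin B12 is scarce, 7 of 9 fell and 0 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.00205). The dietary reporter acdh-1 fell from 1803 ± 9 to 407.1 ± 63.0 CPM (log2 fold change -2.15 ± 0.11 SE), hphd-1 fell by 1.93, ech-6 by 1.69 and hach-1 by 1.53. Genes of glycolysis, gluconeogenesis, glyoxylate and trehalose metabolism fell for 23 of 31 and rose for 3 (23 and 3 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 5.71e-05); gpd-2 fell from 232.4 ± 3.2 to 77.4 ± 3.3 CPM, pfk-1.1 by 1.08 and fbp-1 by 1.11, while tre-5 rose by 4.12. Both lists lost their calls with an estimated correlation (adjusted p = 0.612 with an estimated correlation). The osmotic stress gene gpdh-1 fell by 2.67. In the methionine and one-carbon cycle 10 of 19 fell and 7 rose (10 and 7 adjusted over the list alone; camera adjusted p = 0.265): the folate transporter gene folt-2 fell from 192.1 ± 14.1 to 3.86 ± 1.27 CPM, sams-1 by 1.12 and cth-1 by 1.09, and the phosphocholine synthesis gene pmt-1 rose from 226.7 ± 15.2 to 966.6 ± 44.6 CPM. Digestive and lysosomal proteases had 9 of 23 higher and 9 lower (10 and 10 adjusted over the list alone; camera adjusted p = 0.553; median -0.31, mean 0.02), with asp-14 lower by 2.93 and cpr-6 by 1.5.

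Of the lipases 8 of 13 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0274): lipl-2 rose from 8.51 ± 1.28 to 39.9 ± 2.4 CPM, lipl-3 by 2.63, fil-1 by 3.69 and hosl-1 by 0.89. That call was lost with library size alone (adjusted p = 0.0829), where the median was higher, 0.98 against 0.79, and with an estimated correlation (adjusted p = 0.612 with an estimated correlation). In fatty acid synthesis, elongation and desaturation 13 of 25 fell and 5 rose (13 and 5 adjusted over the list alone; camera adjusted p = 0.0377, and adjusted p = 0.672 with an estimated correlation). The stearoyl-CoA desaturase gene fat-7 fell from 11.3 ± 1.3 to 1.67 ± 0.19 CPM and the palmitoyl-CoA desaturase gene fat-5 by 2.59, whereas the desaturase gene fat-3 of polyunsaturated fatty acid synthesis rose by 2.15. That list was not called without OP50 replicate 2 (0.0675) or *M. furfur* replicate 2 (0.0785). Beta-oxidation and fasting genes had 13 of 37 higher and 11 lower (15 and 12 adjusted over the list alone; camera adjusted p = 0.957; median 0.00, mean -0.14), and 18 higher and 8 lower with library size alone. Within them cpt-3, a carnitine palmitoyltransferase gene, rose from 8.13 ± 3.55 to 92.4 ± 7.8 CPM, kat-1 fell by 1.25, and the fasting reporter acs-2 fell from 147.8 ± 56 to 45.6 ± 8.6 CPM. The level of fmo-2 was 1.67 ± 0.41 and 0.923 ± 0.135 CPM (adjusted p = 0.0639).

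Of the vitellogenins 5 of 6 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.00158). The falls were unequal: vit-4 fell from 3653 ± 232 to 36.6 ± 0.5 CPM, vit-3 from 4148 ± 441 to 212.5 ± 3.6 CPM and vit-1 from 3721 ± 647 to 243.1 ± 25.6 CPM, vit-6 fell by 0.98, and vit-2, the most abundant, stood at 33215 ± 5044 and 28409 ± 4197 CPM (adjusted p = 0.278). These genes are near-identical within the groups vit-3 to vit-5 and vit-1 with vit-2, so reads could be split between copies. In sums chosen after the data were seen, vit-3, vit-4 and vit-5 together fell from 23132 ± 3406 to 10124 ± 959 CPM (log2 fold change -1.19 ± 0.14 SE, adjusted p = 0.000196), and vit-1 with vit-2 had a log2 fold change of -0.37 ± 0.15 (adjusted p = 0.0766). Of the oocyte and eggshell genes 21 of 24 fell and 2 rose (21 and 2 adjusted over the list alone; camera adjusted p = 0.000116), with cpg-9 lower by 3.64, oma-2 by 0.86 and cpg-3 by 0.82. Of the germ cell and meiosis genes 13 of 20 fell and 0 rose (13 and 0 adjusted over the list alone; camera adjusted p = 0.00519), with glh-1 lower by 0.74 and fog-1 by 0.75. With library size alone 14 oocyte genes were lower and 3 higher, and 8 germ cell genes were lower and 3 higher. The 3 calls were lost with an estimated correlation (adjusted p = 0.612 with an estimated correlation for yolk and for oocytes, 0.681 for germ cells). Major sperm protein genes had 1 of 27 lower, msp-50, and 0 higher (0 and 0 adjusted over the list alone; camera adjusted p = 0.118); the list was called as lower without OP50 replicate 1 (0.004) or *M. furfur* replicate 2 (0.000915), and msp-50 was not called without OP50 replicate 2 (0.261) or *M. furfur* replicate 1 (0.244), with upper quartile factors (0.0588), with library size alone (0.0968) or in a robust fit (0.0677). The list was also called as lower with library size alone (0.0136), but camera's direction turned to up without *M. furfur* replicate 1 (0.829). The estimated correlation between these genes was 0.98, at which the adjusted p was 0.776.

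Zygotic embryo genes had 3 of 11 higher and 4 lower (3 and 6 adjusted over the list alone; camera adjusted p = 0.418), and 3 higher and 2 lower with library size alone. The epidermal and muscle fate factors elt-1 and hlh-1 rose by 1.61 and 1.75, and the early factors tbx-37 and pal-1 fell by 1.75 and 0.38 on the log2 scale. Cuticle collagens took 4.48% and 4.90% of all counts in the OP50 libraries and 1.22% and 0.927% in the *M. furfur* libraries, counted over the col genes. Of the collagen genes 45 of 146 fell and 33 rose (45 and 33 adjusted over the list alone; camera adjusted p = 0.091), with a median of -0.09, which became 0.11 with library size alone, and a mean of -0.62. With library size alone camera called the list as lower relative to the other genes (adjusted p = 0.00366 at the preset correlation). At that scaling 36 collagen genes were higher and 41 lower. Without OP50 replicate 1 the median was -0.21. With an estimated correlation the camera adjusted p was 0.719. Moulting genes, which encode the apical matrix and enzymes of cuticle renewal, rose for 9 of 14 and fell for 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00382, and adjusted p = 0.612 with an estimated correlation). There fbn-1 rose from 10.4 ± 0.7 to 67 ± 1.4 CPM, noah-1 from 30.5 ± 0.6 to 117.0 ± 11.2 CPM and noah-2 by 1.71.

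Of the body wall muscle genes 15 of 16 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -1.0 (camera adjusted p = 4.6e-06): the troponin gene unc-27 fell from 851.7 ± 3.6 to 264.5 ± 9.7 CPM, dim-1 by 1.64, pat-10 by 1.61 and mup-2 by 1.58. The remaining gene, the myosin heavy chain gene myo-3, had a log2 fold change of -0.13 ± 0.09 (SE; adjusted p = 0.249), which became -0.27 and a call as lower with the gene length trend removed (adjusted p = 0.0276), and 0.06 with library size alone. Pharynx genes rose for 7 of 12 and fell for 0 (9 and 0 adjusted over the list alone; camera adjusted p = 0.00889), with the pharyngeal troponin gene tnt-4 higher by 0.48 and the myosin gene myo-2 by 0.48; without *M. furfur* replicate 2 myo-2 was not called (0.065). Neuronal genes rose for 8 of 17 and fell for 0 (8 and 0 adjusted over the list alone; camera adjusted p = 0.0485), among them egl-3 by 0.60 and ida-1 by 0.51, which process and store neuropeptides. The neuronal call was lost without OP50 replicate 2 (0.138) or *M. furfur* replicate 1 (0.146). With an estimated correlation the 3 calls were lost (adjusted p = 0.612 with an estimated correlation for body wall muscle and for pharynx, 0.689 for neuronal genes). Intestine genes had 3 of 12 higher and 5 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.521, with a median of 0.06 and a mean of -0.38, and 5 higher and 5 lower with library size alone): the microvillar actin gene act-5 fell from 351.2 ± 21.2 to 80.4 ± 3.6 CPM, pgp-1 by 3.04 and ges-1 by 1.01, and eps-8 rose by 0.55.

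Nuclear hormone receptors rose for 69 of 201 and fell for 17 (66 and 17 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.00205, and adjusted p = 0.612 with an estimated correlation). The counts were 86 higher and 8 lower with library size alone. The receptor gene nhr-25 rose from 5.52 ± 0.19 to 32 ± 0.1 CPM and nhr-35 by 1.90. FMRFamide-like neuropeptide genes rose for 10 of 30 and fell for 0 (9 and 0 adjusted over the list alone; camera adjusted p = 0.00205, and adjusted p = 0.672 with an estimated correlation), with flp-10 higher by 1.69 and flp-14 by 0.56; with library size alone 17 were higher and 0 lower. Insulin-like peptide genes rose for 10 of 28 and fell for 3 (10 and 3 adjusted over the list alone; camera adjusted p = 0.245). There ins-20 had no read in either OP50 library and 3.26 CPM on *M. furfur*, at least 85.7-fold higher against a floor of 3 reads over the OP50 group, and ins-4 rose by 2.46. F-box A genes had 24 of 146 higher and 39 lower (24 and 38 adjusted over the list alone; camera adjusted p = 0.217, 0.0474 with library size alone, and 0.672 with an estimated correlation), with a median of -0.19. Scaled by library size alone, 30 were higher and 28 lower, and the median was 0.00; fbxa-24 rose, fbxa-79 fell by 2.75, and fbxa-72 had a log2 fold change of -4.15.

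Some mitochondrially encoded, ribosomal RNA and histone genes also differed. The RNA was selected on poly(A) beads, so counts of ribosomal RNA need not follow its level in the worms. Genes encoded by mitochondrial DNA fell for 8 of 12 and rose for 0 (8 and 0 adjusted over the list alone; camera adjusted p = 0.0319, and adjusted p = 0.691 with an estimated correlation), with nduo-2 lower by 0.55 and ctb-1 by 0.40. With library size alone 1 gene was higher and 1 lower, and the list was not called (0.0725), nor was it without OP50 replicate 2 (0.0764) or *M. furfur* replicate 2 (0.124), and ctb-1 was not called without *M. furfur* replicate 2 (0.0508) or with library size alone (0.082). Ribosomal RNA took 0.175% and 0.219% of counts on OP50 and 0.324% and 0.498% on *M. furfur*, and in the list of rrn genes 3 of 5, among them rrn-3.56, which is annotated as a pseudogene, rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.265, 0.0289 without *M. furfur* replicate 1, and 0.719 with an estimated correlation), led in abundance by rrn-3.1, higher by 0.91. The call of rrn-3.56 was lost with DESeq2 (0.18) and without OP50 replicate 1 (0.0927) or *M. furfur* replicate 2 (0.236). Histone genes rose for 5 of 28 and fell for 6 (5 and 5 adjusted over the list alone; camera adjusted p = 0.217), and for 6 and 4 with library size alone, with the linker histone gene his-24 rising from 77.1 ± 6.9 to 382.8 ± 15.7 CPM. The fixed gene cyp-14A4 had between 1 and 10 counts per library and was not tested.

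**Figure D3:**
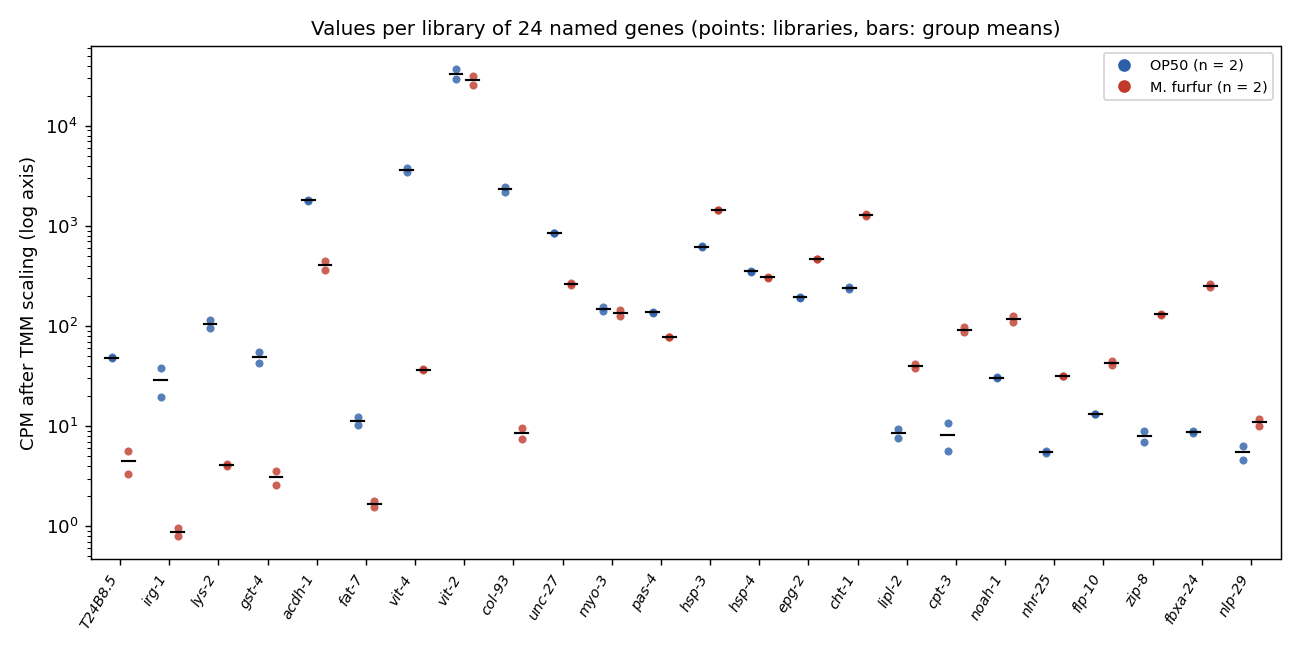
CPM after TMM scaling, on a log axis, of 24 named genes in the 2 OP50 and the 2 *M. furfur* libraries, with points for libraries and bars for group means. The libraries of a group lie close together beside most of the differences, as for acdh-1 at 1803 ± 9 against 407.1 ± 63.0 CPM, while vit-2 and myo-3 were not called.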

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

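Under most of 18 alternatives fixed beforehand the counts of changed genes stayed within 1.5 times of those reported, and genes called in both had 0 changes of sign. With library size alone the genes lower fell to 2333 (5414 higher), which follows from the median shift of 0.19. Testing against a 1.5-fold change left 2828 genes, 1497 higher and 1331 lower, since small changes no longer qualify. A filter of 10 CPM in 2 libraries, which tests 8163 genes, left 1205 genes changed 2-fold or more. Leaving out 1 library at a time gave 2636 to 3256 genes higher, 2619 to 3264 lower, 5255 to 6365 changed in all, 2591 to 2844 changed 2-fold or more, and 19 to 26 lists called; the lone library of a group is then assumed to vary like the other group. Summing vitellogenin copies, chosen after seeing the data, gave 7246 genes. DESeq2 called 3055 genes higher and 3206 lower. For the lists, an estimated correlation called 0 lists against 24, with 1 correlation per list estimated from 2 residual degrees of freedom. Lists with a negative estimate, such as the lipases (-0.03), lost their calls as well, so correlation between genes need not be the reason. The test itself then also rests on those 2 degrees of freedom and could hardly call any list.

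Replicate numbers are shared between groups, but nothing states that they mark a batch. The differences between replicates 1 and 2 correlated at 0.25 (Spearman 0.05) across genes between groups. In the paired fit, with the replicate number as a block, 3808 genes were higher and 3791 lower (7599 in all, 3139 changed 2-fold or more) and 22 lists were called: the endoplasmic reticulum (adjusted p = 0.0576), hypoxia (0.0611) and neuronal (0.0571) lists were not, and major sperm proteins were (1.04e-05). In this paired fit the fasting gene hacd-1 was called as lower (adjusted p = 0.00778), and hsp-4 was not called (0.0965). With the gene length trend removed as well, 3706 were higher and 4001 lower. Of the values of single genes named in the text under the alternatives, 3146 kept direction and call, 61 lost the call, 11 gained it and 19 changed sign; of those of the lists, 404 kept both, 47 lost the call (24 of them with the estimated correlation), 19 gained it and 10 changed direction.

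Apart from hsp-4, which was called as lower, every result that changed direction was uncalled as reported. With library size alone the log2 fold changes were 0.0033 for hsp-4, 0.0938 for zip-2, 0.0736 for hsp-6, 0.1724 for hsp-16.2 and 0.0649 for myo-3, which follows from the shift. For hsp-16.2 they were 0.0116 with upper quartile factors, 0.0001 with the 10 CPM filter, 0.0043 with voom, 0.0589 with the length trend removed and 0.0676 with the block as well. For cht-3 they were -0.006 with RLE factors and with DESeq2, -0.0972 with the length trend removed and -0.0974 with the block as well. Leaving out 1 library at a time gave -0.0733 to 0.0806 for cht-3, -0.254 to 0.2623 for hsp-16.2 and -1.5012 to 0.0793 for hacd-1. List medians then ran from -0.3423 to 0.1167 for C-type lectins, -0.1203 to 0.0579 for heat shock proteins, 0.016 to 0.1296 for beta-oxidation and -1.5609 to 0.2606 for major sperm proteins. Without *M. furfur* replicate 1 the median of the latter was -0.0603, and without OP50 replicate 2 that of heat shock proteins was -0.057, with camera's direction turned in both. Camera's direction also turned with library size alone for heat shock proteins (median 0.1214) and beta-oxidation (0.1978). The fry direction was opposite to camera's for heat shock proteins (median -0.0727), beta-oxidation (0.0024) and zygotic embryo genes (-0.32). Apart from the shift of scale, the cause was not tested. Depth limits genes near the floor of 3 reads (0.0694 to 0.0850 CPM), and 2 libraries per group limit small changes: 48% of simulated 1.5-fold changes were found. That simulation changed 200 of 15956 genes, far fewer than the 45.4% called in the data, so this share need not hold here. It also drew the changed genes from those of at least 1 CPM on OP50, so genes near the floor are not covered.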

Other observations

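All tests of Gene Ontology terms below, the tests on muscle and on fasting genes, the comparison of embryonic transcription factors with other DNA-binding genes, and the choice of the genes named here were made only after the results were seen; the test of embryonic transcription factors and that of their length were set before the values of the 24 genes were looked at, but after the Gene Ontology terms that prompted them. Terms of the deposited annotation were tested with a one-sided Fisher's exact test over 11011 tested genes with a term, for genes changed 2-fold or more, among 1077 terms; these p-values treat genes as independent. Innate immune response led the lower genes, with 81 of 209 members lower by 2-fold or more against 15.7 expected by chance (adjusted p = 6.65e-35), beside 22 members higher by 2-fold or more. Among the higher genes, however, defense response to Gram-positive bacterium (17 of 65, adjusted p = 0.00242) and to bacterium (6 of 11, 0.00853) were enriched, and among the lower genes that to Gram-negative bacterium (18 of 90, 0.00572). The endoplasmic reticulum unfolded protein response was enriched among the higher genes (14 of 50, adjusted p = 0.00466). In contrast, the term PERK-mediated unfolded protein response was enriched among the lower genes (8 of 21, 0.00497). Chitin binding (11 of 30 higher by 2-fold or more, adjusted p = 0.00217) and fucosylation (11 of 24, adjusted p = 0.000263) were enriched among the higher genes, with fut-2, a fucosyltransferase gene, higher by 2.12 on the log2 scale. So was the Cul2-RING ubiquitin ligase complex (14 of 32, adjusted p = 2.41e-05), which includes zeel-1, the antidote of a known toxin-antidote pair that acts in embryos, higher by 3.02. The invertebrate lysozyme gene ilys-3 rose from 0.178 ± 0.004 to 7.4 ± 4.6 CPM (10.6 and 4.12 CPM in *M. furfur* replicates 1 and 2), although most lysozymes that changed were lower.

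Transcription factors stood out among the higher genes: sequence-specific DNA binding had 67 of 328 members higher by 2-fold or more against 28.8 expected (adjusted p = 1.71e-08), and the Notch receptor gene lin-12 rose by 1.72 on the log2 scale. Of noncoding RNA, tts-1, known to be abundant in dauer larvae and long-lived mutants, rose from 41.9 ± 3.6 to 300.1 ± 40.5 CPM, and the Dicer inhibitor RNA rncs-1 rose by 1.78 on the log2 scale, while linc-7 fell by 2.80. The summed CPM of 27 major sperm protein genes was 55.2 and 136.2 in OP50 replicates 1 and 2, and 32.2 and 96.1 in *M. furfur* replicates 1 and 2.

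A hypothesis for the transcription factors is that worms on *M. furfur* held more embryos of later stages. Of 24 transcription factors of later embryos whose single values had not been seen, 20 were higher and 1 (tbx-9) was lower, with a median of 1.39. Among those higher were ceh-36 by 2.98, ceh-43 by 2.08 and unc-130 by 2.66. Part of the 24 belonged to sequence-specific DNA binding, a term that had prompted the test, and for that part the test was not independent. Terms of development were enriched among the higher genes as well. Among them were anatomical structure development (19 of 45, Fisher's exact test adjusted p = 3.49e-07) and cell differentiation (41 of 228, 0.000638). How many of the 24 belonged to such terms was not counted, so independence cannot be assumed for the rest either. The term held 328 tested genes with 122 higher, and 316 with 112 higher once the listed factors were left out. The 316 other genes of sequence-specific DNA binding also rose more often than most: 112 were higher (35.4%) and 36 lower. Of all tested genes 22.85% were higher. Still, 100% of 10000 random lists of these other genes, matched on mean expression, had a lower median than the 24 (at most 0.91). A general rise of DNA-binding genes by the same amount is therefore argued against, but not a smaller one. A bias by gene length is argued against, since all 20 remained higher with the length trend removed. Embryos held longer and induction of the same factors in the adult's own tissues both stay open. The list of zygotic embryo genes did not rise as a whole (3 of 11 higher, 4 lower, median -0.32). It mixes early factors, of which tbx-37 and pal-1 were lower, with fate factors, of which elt-1 and hlh-1 were higher by 1.61 and 1.75. As a whole the list therefore decides neither way.

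Of the body wall muscle genes 15 of 16 were lower, and of the pharynx genes 7 of 12 higher and 0 lower; neither list was called with an estimated correlation (adjusted p = 0.612 for both). With library size alone the muscle median was -0.81, and 14 of 16 muscle genes were still called lower. That scaling moved the tested genes up by a median of 0.19, so this check covers only the choice between scalings. Whether a few abundant transcripts affected both scalings was not tested. A gene length bias is argued against by the muscle median of -1.11 with the length trend removed. The falls were unequal, from -1.69 to -0.13, and 13 of 16 lay over 2 SE from their weighted mean of -1.06, but these SE rest on 2 libraries per group, and the share of each transcript that comes from body wall muscle is not given in the sources used here. One common loss of muscle RNA and regulation that differs between muscle genes therefore both stay open.

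A hypothesis for the lipid genes is that the worms took in less food on the yeast. Of 11 genes known to rise on fasting 6 were higher (cpt-3, fil-1, fil-2, lipl-1, lipl-2 and lipl-3), 3 were lower (acs-2, icl-1 and lipl-5) and 2 were not called (fmo-2 and hacd-1). Both genes known to fall, fat-5 and fat-7, were lower. Changes of lipases, of cpt-3 and of desaturases had prompted the hypothesis, so their directions do not test it. Outside those families acs-2 and icl-1 were lower, and fmo-2 and hacd-1 were not called. The lower call of icl-1 was lost without OP50 replicate 1 (adjusted p = 0.136) or *M. furfur* replicate 2 (0.17), with library size alone (0.136) and with DESeq2 (0.127), and that of lipl-5 without *M. furfur* replicate 1 (0.0506); hacd-1 passed as lower without OP50 replicate 1 (4.97e-05) and with no filter on low counts (0.0386), and changed sign without OP50 replicate 2 (0.0793, adjusted p = 0.793). The higher call of fil-2 was likewise lost without OP50 replicate 1 (0.0611) or *M. furfur* replicate 2 (0.0793). Since part of the set moved against fasting, and no group without food was analysed here, fasting, the change of food and infection cannot be told apart.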
